A study of Homo sapiens with 2 samples.

How the data were processed

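The series holds 2 RNA-seq libraries of HL60-EIF2S3 cells, 1 for each condition. HL60 is an established human promyelocytic leukemia line. In the Tet-Off system a doxycycline-controlled activator drives the transgene while doxycycline is absent, and doxycycline (DOX) shuts it down, so the cells labelled DOX(-) carry the EIF2S3 transgene switched on and those labelled DOX(+) carry it switched off. Per the labels' protocols, total RNA was extracted with Trizol, its integrity was read on a Bioanalyzer, and libraries were built with an NEB Ultra RNA kit for Illumina. Whether polyadenylated RNA was selected or ribosomal RNA removed, whether the libraries kept strand, the read length, the doxycycline dose and the time of treatment were not given in the sources used here.

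The deposited table gives 1 FPKM value (fragments scaled to transcript length and library total) for each gene and library, per the file headers. The submitters' processing notes name CASAVA 1.8, HISAT2 2.1.0, StringTie 1.3.4b and edgeR, and the builds GRCh38 and hg38, with no roles. The parts these tools played, and the annotation release, were not given in the sources used here. The table lists 58302 genes with Ensembl identifiers, symbols, gene types and loci. Of these identifiers, 57980 were found in GENCODE release 29, and 56588 had the same locus there, so transcript lengths, exon overlaps and GC content were taken from that release. GC content was available for 11500 tested genes (99.8%). A symbol shared by several genes (1614 symbols repeated in the table) was taken at its first row.

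The design had been written for counts, and the table held FPKM, so the rules set beforehand for normalized values were used and no count model was fitted. The level of a gene was compared as log2(FPKM + 1) in the library labelled DOX(-) minus the same in the library labelled DOX(+). A pseudocount of 1 FPKM pulls the ratios of low genes towards 0. Genes at 1 FPKM or more in either library were tested. With 1 library per condition the spread between cultures cannot be estimated, so no p-value was made and a rule of size was used: at least 2-fold on the log2(FPKM + 1) scale for single genes, and at least 1.5-fold for counting the members of gene lists. Every value below therefore compares these 2 libraries and has no replicate check.

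FPKM divides by transcript length and library total, which hides depth, so depth was recovered from the values themselves. In genes with 1 annotated transcript the FPKM values are multiples of the value of 1 fragment. The steps gave 16578004 fragments for DOX(-) and 18519439 for DOX(+). At these totals, 99.98% of the values up to 100 fragments in the first library (5551 genes) and 99.97% in the second (5939 genes) came out whole within 0.02 fragment. Counting intervals of ratios are exact conditional 95% intervals (Clopper-Pearson) on fragments estimated from the FPKM and the shortest annotated transcript, a choice that gives the fewest fragments and the widest interval. They cover counting error only, since fragments without molecular identifiers are not independent molecules. The floor of 3 fragments equals 0.181 FPKM in DOX(-) and 0.162 FPKM in DOX(+) for a transcript of 1 kb. Counting error alone was also simulated, with 100 pairs of libraries drawn from the mean FPKM of each gene. The simulation, and its split at a transcript length of 200 nucleotides, were chosen after seeing the data.

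The 34 gene lists (841 symbols, all found in the table) were written from textbook knowledge before the data were examined. For each list the median log2 ratio of its tested members was taken, with an order-statistic 95% interval over members, given for lists of 6 members or more. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins, for lists with 3 or more tested members. These percentiles describe the 2 libraries and are not tests of the conditions. Named genes followed a rule set beforehand: EIF2S3 and the other members of the eIF2 list, the 15 genes with the largest log2 ratio in each direction among protein-coding genes of 5 FPKM or more, in each list the 4 members with the largest difference among those of 2 FPKM or more, and 17 fixed symbols. Other names were chosen after their values were seen: TXNDC5, EIF2S3B, S100A8, CTSG, ELANE, PRTN3, and EEF1A1, RPL41 and RPL13A with their pseudogenes. Genes of lists other than the main ones are named in part, and 1 gene is not reported here. Lists of known MYC target genes and of ribosomal protein pseudogenes were added after seeing the data.

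Alternatives covered the pseudocount, the filter, the size threshold, 3 scalings between libraries, protein-coding genes only, genes free of overlapping gene models, the counting interval, the mean of list members and lists without shared members. The statistics were tested on simulated data, with fragments drawn on the longest annotated transcript. All changes were placed in genes with a mean of 5 FPKM or more. Of 200 such genes changed 4-fold, among 11584 tested genes, 99.5% passed the 2-fold rule. Through counting error, 155 unchanged genes passed it. A list of such genes shifted by 0.30 on the log2 scale came back at 0.29. Recovery in lower genes, whose ratios the pseudocount shrinks, was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.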

Results

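The transcriptomes of HL60-EIF2S3 cells grown without and with doxycycline were compared, 1 RNA-seq library each, to ask how overexpression of EIF2S3, the gamma subunit of the translation initiation factor eIF2, relates to gene expression and to the cell cycle in a leukemia line. The library labelled DOX(-) held 16578004 fragments and the library labelled DOX(+) 18519439, so that 1 FPKM stood for 16.6 and 18.5 fragments per kb of transcript. FPKM values above 0 were listed for 20435 genes in DOX(-) and 21304 genes in DOX(+), and 11525 genes reached 1 FPKM in at least 1 library, 9283 of them protein-coding. Across these genes the log2 values of the libraries had a Pearson correlation of 0.974, where genes are not independent replicates. In each pair of FPKM values below, the library labelled DOX(-) comes first, and ratios are DOX(-) over DOX(+). Log2 ratios and the 1.5-fold and 2-fold rules use FPKM + 1, while other ratios are of plain FPKM. Low genes can therefore differ 1.5-fold by plain FPKM and still count as within 1.5-fold.

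EIF2S3 itself was listed at nearly equal levels. The gene (ENSG00000130741, chromosome X, 24054716 to 24077971, GRCh38) stood at 132.9 FPKM in DOX(-) and 126.2 FPKM in DOX(+), a ratio of 1.05 with a counting interval of 0.927 to 1.196. The higher EIF2S3 level that the labels give to DOX(-) was therefore not seen in these values, and the conditions are named below as the libraries labelled DOX(-) and DOX(+). Doxycycline itself differs between the libraries too, and doxycycline-treated cells without the transgene were not analysed here. EIF2S1 and EIF2S2, the alpha and beta subunits, were at 31.8 and 35.0 FPKM and at 55.2 and 59.8 FPKM. All 19 members of the list of eIF2 and its regulators lay within 1.5-fold on the log2(FPKM + 1) scale, though EIF2AK3 differed 1.69-fold by plain FPKM. Their median log2 ratio was -0.00 (interval -0.13 to 0.14), at percentile 48.0 of matched random lists. The sign of this median turned with the scaling, to 0.01 under median-of-ratios scaling and 0.02 under trimmed-mean scaling. The members that differed most were EIF2AK3, the eIF2 kinase PERK (3.33 and 1.97 FPKM, log2 ratio 0.55), EIF5B, a factor of ribosomal subunit joining (33.0 and 46.8 FPKM, -0.49), and EIF2B3, a subunit of the eIF2 exchange factor (22.4 and 17.9 FPKM, 0.31). The counting interval of the EIF2AK3 ratio, 0.924 to 3.22, included equal levels, and that of EIF5B, 0.611 to 0.815, did not. The other kinases had log2 ratios of 0.18 (EIF2AK1), -0.18 (EIF2AK2) and 0.14 (EIF2AK4), and the other eIF2B subunits -0.17 (EIF2B1), -0.00 (EIF2B2), -0.01 (EIF2B4) and 0.19 (EIF2B5). The phosphatase subunits PPP1R15A and PPP1R15B were at 0.09 and -0.15, EIF5 at -0.11, and CDC123, EIF2A and EIF2D at 0.02, -0.01 and 0.01. The signs of EIF2B2, EIF2B4, EIF2A and EIF2D turned under at least 1 scaling.

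MYC, the transcription factor gene that is amplified in HL60, was the named gene with the largest difference on the log2(FPKM + 1) scale outside overlapping gene models. It stood at 29.5 FPKM in the library labelled DOX(-) and 2.06 FPKM in the one labelled DOX(+) (chromosome 8, 127735434 to 127741434). The ratio of these FPKM values was 14.3, with a counting interval of 8.27 to 27.8 that covers counting error only. MYC has several annotated transcripts of unequal length, and a different division of reads between them could also change its FPKM. This was not tested for MYC, and the same limit holds for the other genes named in this paragraph. Also higher in DOX(-) were MRFAP1 (39.5 and 7.84 FPKM, log2 ratio 2.196), the phosphatase gene PDXP (11.3 and 2.31 FPKM, 1.897), the chemokine gene CCL5 (31.8 and 8.39 FPKM, 1.805), MPZL1 (8.63 and 1.85 FPKM, 1.76), TMEM230 (23.7 and 7.45 FPKM, 1.546), WDFY1 (17.0 and 5.53 FPKM, 1.47) and TMEM101 (8.94 and 2.93 FPKM, 1.34). Lower in DOX(-) were TENT5A, which encodes a poly(A) polymerase (3.32 and 28.0 FPKM, -2.75), ANXA2R (0.414 and 7.13 FPKM, -2.52, or 17.2-fold by plain FPKM), the mitochondrial ribosomal protein gene MRPL34 (3.24 and 17.7 FPKM, -2.14), the sialidase gene NEU3 (0.880 and 6.84 FPKM, -2.06), SURF4, which encodes a cargo receptor of the secretory pathway (8.80 and 36.4 FPKM, -1.93), and JUND, an AP-1 subunit gene (4.19 and 15.5 FPKM, -1.67). The sulfotransferase genes CHST14 (1.502 and 6.90 FPKM, -1.66) and CHST11 (3.87 and 13.1 FPKM, -1.53) were lower in DOX(-) as well, as were FAM13B (3.28 and 11.1 FPKM, -1.51) and TOR1AIP1 (2.01 and 7.38 FPKM, -1.47).

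Several of the 30 largest differences sat in gene models that share exons on the same strand with another listed gene (12 of 30). AC120057.2, which overlaps GABARAP and CTDNEP1, was at 36.2 FPKM in DOX(-) and listed at 0 in DOX(+). The readthrough gene BLOC1S5-TXNDC5 was listed at 0 in DOX(-) and at 54.4 FPKM in DOX(+), while TXNDC5, whose exons it shares and which was named after its values were seen, was at 88.5 and 55.3 FPKM. AC004922.1, which overlaps ARPC1A and ARPC1B, was at 19.998 and 1.07 FPKM, and AC104109.3, which overlaps SKP1 and PPP2CA, at 0.624 and 10.6 FPKM. The others were AC068580.4 (38.8 and 3.74 FPKM), FP565260.2 (6.38 FPKM and listed at 0), AC010323.1 (20.3 and 2.42 FPKM), IL10RB (15.1 and 4.59 FPKM), AC007240.1 (1.904 and 9.39 FPKM), MOB4 (1.63 and 6.41 FPKM), and MFSD14A (22.9 and 8.84 FPKM) with its overlapping partner AC118553.2 (0.536 and 6.22 FPKM). Values of such genes are uncertain, since fragments of shared exons can be assigned to either model.

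By the rule of size, 96 of the 11525 genes were at least 2-fold higher in the library labelled DOX(-) and 138 at least 2-fold lower, and 11291 lay within 2-fold. Libraries drawn with no difference gave a mean of 226 such genes (highest draw 262) when counted on the shortest transcripts and 171 (highest draw 204) on the longest, so the total of 234 lay within the first range and above the second. Most of the simulated genes had a transcript of 200 nucleotides or less. Among the 10915 tested genes without one, 157 differed 2-fold, against a simulated mean of 41.5 on the shortest transcripts, and among the 610 with one, 77 differed, against 184.7, so the simulation gave too many there and the agreement of the totals is of little weight. Among 5128 protein-coding genes of 5 FPKM or more, 77 differed 2-fold (35 higher, 42 lower), against a simulated mean of 7.03 and a highest draw of 14.

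**Figure D1:**
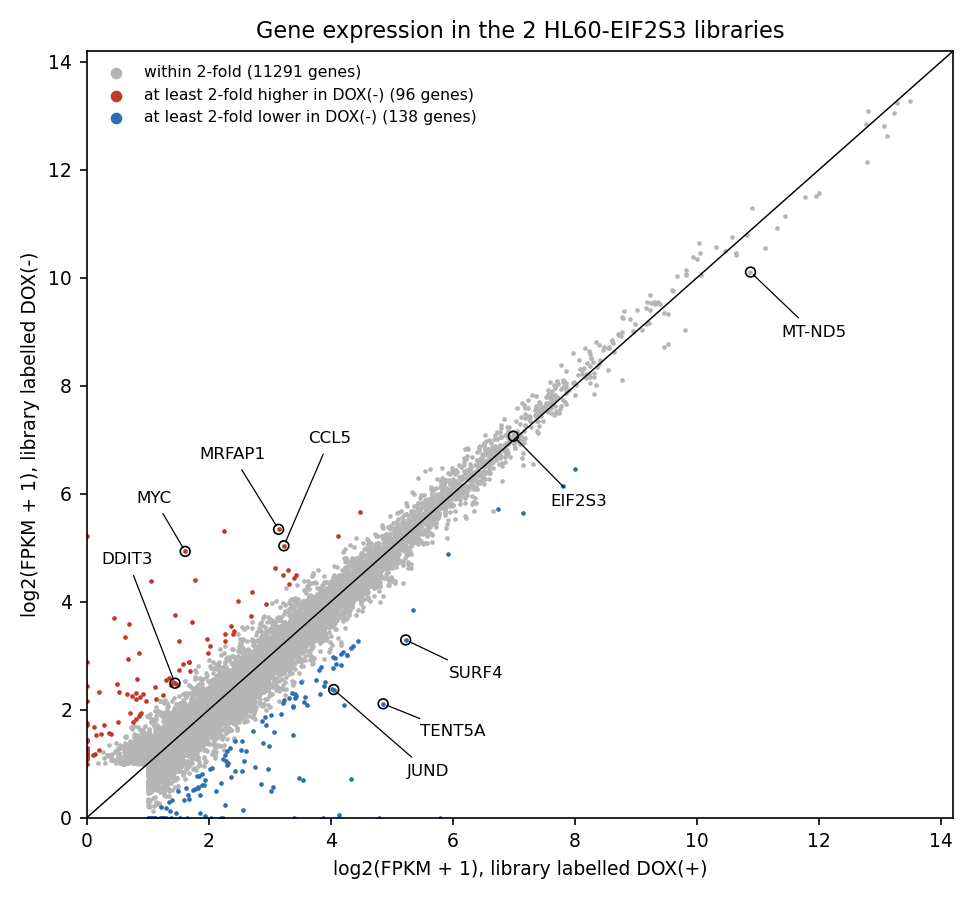
Expression of the tested genes in both libraries, as log2(FPKM + 1) with DOX(+) on the horizontal and DOX(-) on the vertical axis, 1 point per gene. Red points are the 96 genes at least 2-fold higher and blue points the 138 genes at least 2-fold lower in the library labelled DOX(-), and EIF2S3 lies among the 11291 grey genes within 2-fold.

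For the cell cycle, which the series title names, the lists differed little between the libraries apart from MYC. Among 20 tested G1 and G1/S regulators, 1 (MYC) was at least 1.5-fold higher in DOX(-) and none was 1.5-fold lower. Their median log2 ratio was -0.04 (interval -0.23 to 0.07, percentile 35.9), and their mean was 0.08, of the opposite sign, or -0.09 without MYC. Cyclin gene CCNE2 was at 3.96 and 5.65 FPKM, CDK6 at 19.0 and 25.7 FPKM and CCND3 at 14.3 and 11.2 FPKM. CCND2 was at 26.7 and 29.4 FPKM, CCNE1 at 3.74 and 4.69 FPKM, and CCND1 at 0.266 and 0.284 FPKM, with a counting interval of 0.0810 to 15.4 for the ratio. Of 51 DNA replication genes, 1 was 1.5-fold higher, the licensing factor CDT1 (46.9 and 30.2 FPKM, log2 ratio 0.62), and the median was -0.04 (interval -0.10 to 0.01, percentile 16.6). ORC2 was at 7.32 and 5.29 FPKM, UHRF1 at 10.3 and 13.3 FPKM and MCM10 at 8.49 and 10.7 FPKM. PCNA, the sliding clamp of replication, was at 286.7 and 315.7 FPKM, and the 6 genes of the MCM2-7 helicase had log2 ratios between -0.11 and 0.09. Of 42 genes of G2/M and mitosis, 27 were below 0 and 1 was 1.5-fold lower, the kinetochore motor gene CENPE (2.99 and 5.75 FPKM, -0.76), with a median of -0.08 (interval -0.12 to 0.00, percentile 3.17). CCNB1 was at 39.8 and 41.7 FPKM, CDK1 at 7.32 and 8.72 FPKM, the proliferation marker MKI67 at 30.8 and 32.8 FPKM, and WEE1, the kinase that restrains CDK1, at 1.79 and 3.18 FPKM. NDC80 was at 12.9 and 17.9 FPKM and CENPF at 7.96 and 10.9 FPKM. The 6 tested CDK inhibitors all lay within 1.5-fold (median 0.09, interval -0.25 to 0.38, percentile 85.5). CDKN1A was at 2.43 and 2.31 FPKM, CDKN1B at 11.5 and 13.8 FPKM, CDKN2C at 13.2 and 9.94 FPKM, CDKN2D at 2.38 and 1.85 FPKM and CDKN3 at 9.31 and 8.58 FPKM. The ratios of CCNE2, CCND2, CCND3, CCNE1, CCNB1, CDK1, MKI67, WEE1, ORC2, MCM10, NDC80, CENPF, CDKN1A, CDKN1B, CDKN2D and CDKN3 had counting intervals that included equal levels.

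Targets of ATF4 and the integrated stress response, the pathway that phosphorylation of eIF2 sets off, were mostly higher in the library labelled DOX(-). Of 30 tested members, 25 had a log2 ratio above 0, 6 were at least 1.5-fold higher and none was 1.5-fold lower, with a median of 0.27 (interval 0.11 to 0.47, percentile 100). DDIT3, which encodes CHOP, was at 4.63 and 1.73 FPKM (ratio 2.68, counting interval 1.53 to 4.58). SESN2 and DDIT4, both negative regulators of mTORC1 signalling, were at 19.1 and 8.98 FPKM and at 77.0 and 42.3 FPKM. CTH, of cysteine synthesis, was at 5.81 and 3.15 FPKM, ATF4 itself at 100.7 and 71.7 FPKM (ratio 1.40, 1.32 to 1.49) and the asparagine synthetase gene ASNS at 6.36 and 4.33 FPKM (ratio 1.47, 0.977 to 2.21). In the list of endoplasmic reticulum chaperones and the unfolded protein response, 2 of 22 genes were 1.5-fold higher, HERPUD1 (3.91 and 2.16 FPKM, a ratio whose counting interval of 0.973 to 3.58 included equal levels) and XBP1 (14.5 and 9.22 FPKM), with a median of 0.10 (percentile 91.4).

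Cytosolic ribosomal protein genes were slightly and broadly higher in DOX(-). Of 78 genes, 68 were above 0 and 3 were at least 1.5-fold higher, and the median was 0.21 (interval 0.16 to 0.26, percentile 100). RPL37 was at 87.2 and 48.3 FPKM and RPS28 at 35.1 and 20.3 FPKM. Values of this family are uncertain because it has many processed pseudogenes: RPL13A was at 68.9 and 54.2 FPKM while its pseudogene RPL13AP5 was listed at 2509 and 1921 FPKM. Of 28 other translation initiation factors, 1 was 1.5-fold higher, EIF1 (14.7 and 8.94 FPKM), and EIF4B was at 135.0 and 91.1 FPKM, with a list median of 0.11 (percentile 95.4). Ribosome biogenesis genes did not follow the ribosomal proteins: of 30 genes, 2 were 1.5-fold lower in DOX(-), NIP7 (3.69 and 11.0 FPKM) and RRS1 (50.4 and 80.3 FPKM), and the median was -0.04 (percentile 15.3).

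The 13 protein-coding transcripts of the mitochondrial genome were all lower in the library labelled DOX(-), 3 of them at least 1.5-fold, with a median of -0.31 (interval -0.65 to -0.20, percentile 0). MT-ND5 was at 1099 and 1878 FPKM, MT-ND6 at 273.6 and 435.7 FPKM, and MT-ATP8 at 4492 and 7072 FPKM. Mitochondrial genes took 22.5% of all FPKM in DOX(-) and 27.7% in DOX(+). Nuclear genes of oxidative phosphorylation had a median of 0.02 over 44 genes (percentile 51.2), with COX7C at 3.34 and 8.25 FPKM and NDUFB8 at 17.9 and 11.5 FPKM, and mitochondrial ribosomal proteins a median of -0.03 over 37 genes (percentile 24.98). Mitochondrial tRNA genes (22 genes, median -0.998, interval -1.25 to -0.71) and snoRNA genes (105 genes, -0.36, interval -0.45 to -0.08) were also lower in DOX(-). Other classes of small RNA genes had intervals that included 0, with medians of -0.33 over 24 snRNA genes (-0.69 to 0.50), -0.196 over 36 miscellaneous RNA genes (-0.45 to 0.29) and 0.04 over 84 miRNA genes (-0.28 to 0.08). The 4 tested replication-dependent histone genes were all below 0 (median -0.51, percentile 0.490, or -0.15 without the low-value filter), among them HIST1H2BK (13.9 and 21.97 FPKM).

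Of 13 hypoxia response genes, 3 were 1.5-fold higher in DOX(-), MXI1 (4.49 and 1.81 FPKM), NDRG1 (19.9 and 11.4 FPKM) and DDIT4, which the ATF4 list also holds. The median of the hypoxia list was 0.19 (percentile 99.5), with an interval of -0.17 to 0.75 that included 0. The 16 genes of heat shock and cytosolic chaperones had a median of -0.22 (percentile 0.0100), with an interval of -0.33 to 0.04 that included 0. All lay within 1.5-fold, with DNAJB1 at 13.3 and 18.8 FPKM and HSPA8 at 258.4 and 325.0 FPKM. Of 17 NRF2 and oxidative stress genes, 3 were 1.5-fold lower, GCLM (3.17 and 6.99 FPKM), PRDX1 (92.7 and 158.8 FPKM) and TXN (91.7 and 141.1 FPKM), with a median of -0.09 (percentile 9.11). No gene of glycolysis (21 genes, median 0.13, percentile 95.5) or of cholesterol biosynthesis (21 genes, 0.08, percentile 92.0) differed 1.5-fold on the log2(FPKM + 1) scale. The same held for the p53 targets (17 genes, 0.05, percentile 88.4) and the NF-kappaB and inflammatory list (10 genes, 0.04, percentile 82.4). Pro-apoptotic genes had a median of -0.10 over 18 genes (percentile 16.3), and 1 of them, BCL2L11, was 1.5-fold higher (2.23 and 1.14 FPKM). The counting interval of its ratio, 0.605 to 7.64, included equal levels. Anti-apoptotic genes had a median of -0.16 over 9 genes (percentile 13.6), and 1 was 1.5-fold lower, BIRC2, an inhibitor of apoptosis, at 0.855 and 2.46 FPKM. Of 12 interferon-stimulated genes, IFIT3 (2.28 and 6.63 FPKM) and IFI6 (6.37 and 10.4 FPKM) were 1.5-fold lower (median -0.14, percentile 9.10). Immediate early genes went both ways, with MYC higher and JUND and FOSL2 (1.13 and 3.70 FPKM) lower among 16 genes. Their median was 0.13 (interval -0.32 to 0.25, percentile 98.6), or -0.00238 without the low-value filter.

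Myeloid genes showed no common direction. The 18 tested promyelocyte and azurophil granule genes had a median of -0.01 (percentile 20.3), with the granule protein gene AZU1 at 76.0 and 52.3 FPKM and RNASE2 at 106.3 and 141.2 FPKM. Of 13 neutrophil maturation genes, 2 were 1.5-fold lower in DOX(-) and none 1.5-fold higher (median -0.13, percentile 10.4), the calprotectin subunit genes S100A9 (19.8 and 32.0 FPKM) and S100A8 (0.0887 and 1.59 FPKM, named after its value was seen). The S100A8 value in DOX(-) lay below the floor of 3 fragments, and its ratio had a wide counting interval of 0.00177 to 0.484. CEBPE, at 8.93 and 12.6 FPKM, was within 1.5-fold. Of 10 monocyte and macrophage genes, IRF8 (18.9 and 9.94 FPKM) and MARCO (2.89 and 1.43 FPKM) were 1.5-fold higher and CD36 (1.201 and 3.28 FPKM) lower. The median of this list was 0.19 (interval -0.47 to 0.68, percentile 98.7), or -0.00641 without the low-value filter. The differentiation markers ITGAM (0.584 and 0.629 FPKM) and CD14 (0.0626 and 0.0700 FPKM) were low in both libraries. Markers of other cell types were few. Among 5 erythroid markers, HBA1 (1.33 and 3.36 FPKM) and HBG1 (5.06 and 8.60 FPKM) were lower in DOX(-) (median -0.37, percentile 0.885, or -0.23 without the low-value filter). Among 3 markers of eosinophils, basophils and mast cells, the tryptase genes TPSAB1 (7.24 and 2.98 FPKM) and TPSB2 (4.55 and 1.75 FPKM) were 1.5-fold higher. FCER1A (1.42 and 2.45 FPKM) was within 1.5-fold on the log2(FPKM + 1) scale. The list median was 1.01 (percentile 99.98), or -0.0330 without the filter. This median is the value of TPSB2, which lies close to TPSAB1 on chromosome 16, so the percentile rests on 1 pair of neighbouring genes. The T and NK cell list had 2 tested members, NKG7 (19.4 and 12.6 FPKM) and CD4 (42.8 and 36.9 FPKM), the B cell list 1 at 1.66 and 0.709 FPKM, and the megakaryocyte list 1 at 1.305 and 1.19 FPKM. No fibroblast or epithelial marker was above 0.198 FPKM. Of the 30 lists with 3 or more tested members, 10 lay outside the central 95% of their random lists (6 above, 4 below). Chance gives 1.5 if lists, and genes within a list, vary independently. Members of a list can vary together between any 2 cultures, so an excess over chance cannot be read from this count. Of these 10, only ATF4 targets, ribosomal proteins and mitochondrial transcripts had an interval over members that excluded 0, and lists under 6 members had none. With random lists matched on GC content and length of the longest annotated transcript as well, 10 lay outside and 8 of them were shared. Erythroid markers (percentile 4.495) and immediate early genes (94.4) then lay inside, and the endoplasmic reticulum list (98.9) and the other translation initiation factors (99.7) outside.

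**Figure D2:**
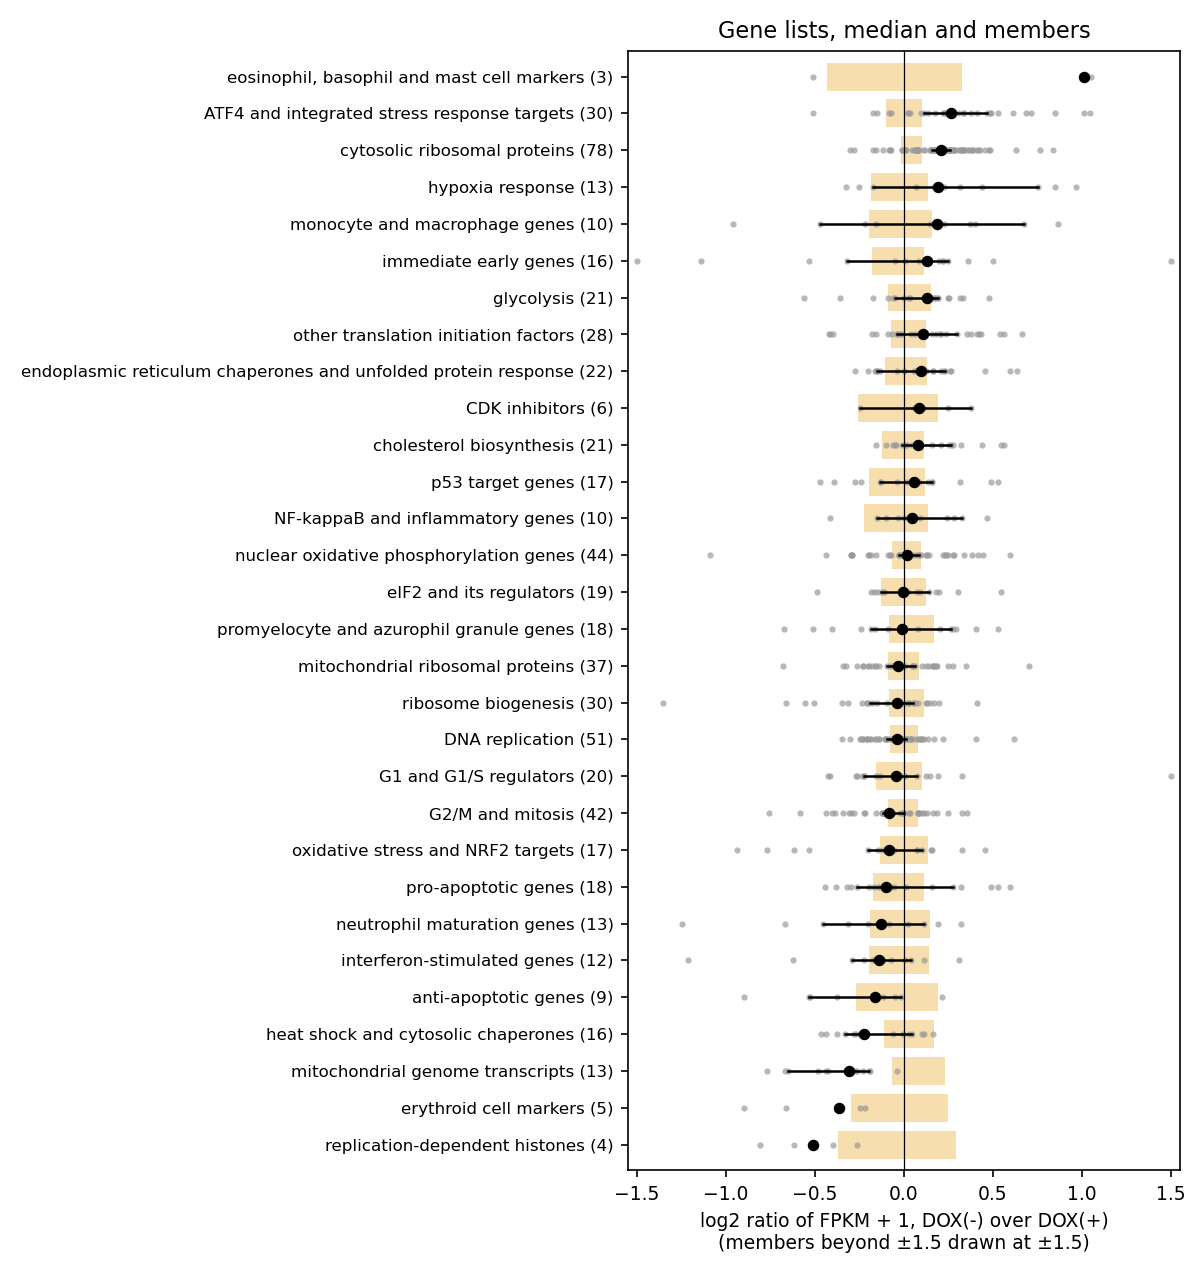
Median log2 ratio of FPKM + 1, DOX(-) over DOX(+), for the 30 gene lists with 3 or more tested members (number in brackets). Black dots are medians, lines their 95% intervals over members (lists of 6 or more), grey dots the members (drawn at the edge when beyond it), and orange bands the central 95% of random lists matched on expression; the ATF4 target list (0.27) and the cytosolic ribosomal proteins (0.21) lie above their bands and the mitochondrial genome transcripts (-0.31) below theirs.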

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

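The trimmed-mean scaling and the restriction to genes without overlapping gene models were chosen after seeing the data. EIF2S3 kept a log2 ratio between 0.06 and 0.10 under the other pseudocount and all 3 scalings, which removed log2 shifts of -0.01 (median of ratios), -0.03 (trimmed mean) and 0.01 (without mitochondrial and the 20 most abundant genes) from all genes. The 3 scalings left the counts of 96 higher and 138 lower genes within 1.5 times. Removing the low-value filter could not change these counts. With a pseudocount of 1 FPKM, a gene below 1 FPKM in both libraries cannot reach 2-fold. The counts were 247 and 307 with a pseudocount of 0.1, which shrinks low genes less, 358 and 468 at 1.5-fold, 42 and 66 above 5 FPKM, 54 and 74 among protein-coding genes, and 40 and 58 where the whole counting interval lay past 2-fold. Without overlapping gene models, 57 genes were higher and 97 lower. Fewer genes were tested under these filters. The mean of the G1 and G1/S regulators was 0.0842, against a median of -0.04, through MYC alone (-0.09 without it). With no low-value filter the medians of immediate early genes (-0.00238), monocyte and macrophage genes (-0.00641) and eosinophil, basophil and mast cell markers (-0.0330), which lay outside their random lists, turned negative with low genes added, as did those of NF-kappaB and inflammatory genes (-0.00990) and megakaryocyte markers (-0.0674). Of 328 alternative values of list medians, 310 lay within the interval over members (the range, for lists under 6 members), 15 lay outside it and 3 were the reversals of lists outside their random lists. In all, 14 of the 328 changed sign, among them the eIF2 list, the promyelocyte list (0.02 under trimmed-mean scaling) and the p53 targets (-0.26 above 5 FPKM). Of 688 values for single genes, 677 stayed within the width of their counting interval and 11 did not, and 6 changed sign, all in EIF2A, EIF2B2, EIF2B4 and EIF2D, which stood near 0. Count-based scalings and size factors from counts were not run, as the table holds FPKM. No paired analysis was possible because each condition has 1 library. Depth limits values near 0.181 and 0.162 FPKM for a 1 kb transcript.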

Other observations

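Of the tests below, those of overlapping gene models, of protein-coding genes above 5 FPKM, of EIF2S3 and of poly(A) selection were chosen after the result was seen, and the lists of MYC targets and ribosomal protein pseudogenes were added after seeing the data.

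Several genes were listed at levels that stand apart from close relatives in both libraries. MPO, the myeloperoxidase gene for which HL60 is known, was at 0.274 and 0.469 FPKM, while genes of the same granules, chosen after their values were seen, were high: CTSG at 689.2 and 569.8 FPKM, ELANE at 396.4 and 299.4 FPKM and PRTN3 at 177.6 and 144.7 FPKM. EEF1A1 was at 285.5 and 303.9 FPKM and its processed pseudogene EEF1A1P5 at 8724 and 7146 FPKM. RPL41 was at 17.5 and 17.5 FPKM and RPL41P1 at 1771 and 1812 FPKM. Pseudogenes together held 27.1% and 24.0% of all FPKM. The levels of MPO and of these gene and pseudogene pairs are uncertain as measures of expression, since how fragments were assigned to them was not tested.

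Large differences of single genes, MYC among them, were the first pattern. Overlapping gene models may account for part of it: 34.2% of the 234 genes that differed 2-fold (exact interval 28.1% to 40.7%) shared exons with another tested gene, against 7.93% of all tested genes. Of their partners, 63.3% (53.5% to 72.3%) differed in the opposite direction, against 52.1% of the partners of all tested genes. This interval is too narrow, since a gene can enter it more than once. Among protein-coding genes of 5 FPKM or more the overlapping share was 28.6%, against 7.20%, which leaves most of the 77 genes, MYC included, without such a partner. Counting error is argued against as the whole cause, since intervals excluded equal levels for 75.2% of the 234 genes (21.6% in a simulated pair without difference) and, widened for the number of genes, for 80.5% of the 77, although the total of 234 lay within the draws on the shortest transcripts (highest 262), where the simulation gave more short-transcript genes than the data (184.7 against 77) and fewer longer ones (41.5 against 157). Division of reads between transcripts of unequal length cannot be told apart. Among protein-coding genes of 5 FPKM or more without an overlapping partner, 4.84% of 4438 with several transcripts and 4.73% of 317 with 1 differed 1.5-fold. Lower MYC-dependent transcription in DOX(+) is argued against only for the added list of 54 known MYC targets, with a median of -0.0903 (interval -0.18 to 0.01, percentile 0.520). Other genes that depend on MYC, and MYC protein, were not tested.

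The nearly equal EIF2S3 values were the second pattern. An exchange of labels would not by itself make the values equal: EIF2S3 would be at least 1.5-fold higher in DOX(+), which a ratio of 1.05 (0.927 to 1.196) does not show. Whether the labels were exchanged cannot be told from these values, since EIF2S3 was not clearly higher in either library than in the other. Transgene reads assigned to the near-identical gene EIF2S3B (chromosome 12, 10505602 to 10523135) are argued against if the labels hold. EIF2S3B was at 0.226 and 1.54 FPKM, a ratio of 0.146 (0.0509 to 0.342) in the wrong direction. With exchanged labels the direction would not argue against it, but in both libraries EIF2S3B lay far below EIF2S3 (132.9 and 126.2 FPKM). A transgene that was silent, one whose sequence differs from the counted exons, and a loss of overexpression in culture stay open and were not tested. Equal values also cannot tell a transgene off in both libraries from one on in both, since cells without the transgene were not analysed here.

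Shifts of whole lists, with ATF4 targets and ribosomal proteins higher and mitochondrial transcripts lower in DOX(-), were the third pattern. GC content and length of the longest annotated transcript are argued against: among random lists matched on these as well, the percentiles were 100 for ATF4 targets, 100 for ribosomal proteins and 0.0150 for mitochondrial transcripts. The longest transcript need not be the one expressed: those of RPL37 run from 425 to 7686 nucleotides. A bias by the expressed transcript therefore stays open for nuclear genes. Expression was matched in 5 bins here, which is coarse for the abundant mitochondrial transcripts. Ribosomal protein pseudogenes were higher too (median 0.20 over 156 genes, interval 0.16 to 0.29), which argues against fragments moving from pseudogenes to their parents. Less complete selection of polyadenylated RNA in DOX(+), if such selection was made, may contribute to the mitochondrial shift, as snoRNA and snRNA genes had a median of -0.36 (interval -0.43 to -0.08). The 24 snRNA genes alone (-0.33, interval -0.69 to 0.50) do not decide. Replication-dependent histone genes, for which the same was predicted, had a median of -0.51, or -0.15 without the low-value filter. With 4 tested members they have no interval, so this part of the prediction is undecided. Most mitochondrial mRNAs also carry poly(A) tails themselves. An effect of doxycycline, which inhibits mitochondrial translation, an effect of the transgene, and a difference in culture density stay open, untested and inseparable with 1 library each.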
